A study of Mus musculus with 12 samples.

How the data were processed

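RNA was collected from sorted motor neurons of control and Pbx mutant embryos at E12.5, with 4 groups of 3 libraries. Per the labels' protocols, cords were cut into brachial and thoracic pieces, meninges and dorsal root ganglia were removed, cells carrying the Hb9::GFP reporter were sorted, and the cDNA was amplified before library construction. Per the submitters' processing notes, Bowtie 1.0.0, Picard 1.88, HTSeq 0.6.1p1 and DESeq2 1.12.3 and the builds NCBIM37 and mm9 were used. The settings of these tools, and whether counting used strand, are not given in the sources used here. Overlapping and antisense genes are therefore uncertain.

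The authors deposited 3 tables, 1 per comparison, each holding only the genes they kept. The per-library columns, called CPM in the sheet titles, behave as a normalized signal, that is read counts divided by 1 factor per library: their row mean equals the authors' mean column, and 100% of the nonzero values in each library are whole multiples of 1 step within a tolerance of 1e-06. The planned tests assumed CPM, and the same limma test was used on this unit. Library totals were not analysed here. Each table was normalized separately by the authors. A control library that stands in 2 tables differs between them by 1 constant factor, so each difference between groups was taken within a table. The interaction test compares such differences between 2 tables, and it and levels set across tables carry this limit. The log2 fold changes, their standard errors, the test scores and the p-values were deposited by the authors from their own model. In the brachial mutant table the authors' log2 fold changes were 0.68 times the log2 ratio of group means at the median, against 0.998 in the thoracic one, so differences printed here are recomputed from the normalized counts. From p-values and adjusted p-values, the authors tested 13708, 16235 and 11847 genes between control levels, in the thoracic and in the brachial mutant comparison. The thoracic and brachial tables each list 1 gene with an adjusted p over 0.05.

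Values were taken as log2(normalized count + 0.5), with no filter on low values, and fitted with limma 3.58.1 in R 4.3.3 with 2 groups per table and Benjamini-Hochberg adjustment over the genes of the table, with a threshold of 0.05. The effect of genotype was compared between levels by a limma interaction over the 12 libraries for the 30 genes of both mutant tables. In simulated data of 1000 genes, the fit recovered 18%, 61% and 85% of the genes changed 1.5-fold for control levels, thoracic and brachial mutants, and 100% of those changed 3-fold, and called 6, 5 and 9 of 800 unchanged genes. The interaction fit recovered 91% of extra 2-fold effects. That simulation used the smaller dispersion of the 2 mutant tables, 0.013 (brachial) against 0.020 (thoracic), at both levels. It can therefore overstate the recovery for noisier genes, such as Arhgap36 with an interaction SE of 0.61. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 3.81 and 19.1. This covers counting error only and, since the cDNA was amplified, does not show that the libraries are separate samples.

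The choices of groups, tests, 19 gene lists and most alternative settings were made before the data were examined. The text names the Pbx genes, the 8 largest differences in each direction among genes whose groups do not overlap, the members of each fixed list (all if 6 or fewer, otherwise the 4 largest), and up to 8 genes per pair of tables, without predicted genes. Some genes that this rule names are not reported here. Genes of the largest lists, and genes beside Hox clusters, immediate-early genes, Spry2, Col2a1, Gm13404 and those that did not pass, are also named after their values were seen. Lists with no listed member in any table were dorsal root ganglion and neural crest, blood and endothelial, and sex-linked genes. All 205 gene identifiers matched the reference names, and 4 had another symbol there. Gene order and exon overlap were taken from GENCODE on GRCm38 and no coordinates are given, since the notes name another build. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps. Alternatives were pseudocounts of 0.1 and 2, a minimum mean of 1, the replicate letter as a block, leaving out each library, centring on the median listed gene, an intensity trend, and stricter limits on the authors' values.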

Results

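Gene expression was measured by RNA sequencing in mouse spinal motor neurons of E12.5 embryos, sorted by a green fluorescent reporter driven by the motor neuron gene Hb9. The cells came from brachial cord, which innervates the forelimb, or thoracic cord, which innervates the body wall and the sympathetic ganglia. Controls were compared with embryos that carried a motor neuron mutation of Pbx genes, which encode homeodomain cofactors of Hox proteins. Each of the 4 groups had 3 libraries, named A, B and C. The 3 deposited tables listed 205 different genes, already selected by the authors on these libraries, so the limma p-values below describe the spread among replicates within each list and are not independent evidence of change. The series design names 9 pooled controls and 9 mutants and does not say how these were divided over the libraries. Nothing in the labels says that the libraries of a group came from separate embryos, and the p-values measure only the spread between libraries. If 1 step of the normalized counts is 1 read, the listed genes held between 14181 and 17457 reads per library between control levels, between 50690 and 81370 in the thoracic mutant comparison and between 39381 and 52090 in the brachial one.

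Control brachial and thoracic motor neurons differed in 10 listed Hox genes and in listed genes of motor columns. Hoxc6, a brachial Hox gene, averaged 1889 ± 98.5 normalized counts (SD, n = 3) at the brachial level and 760.2 ± 14.5 at the thoracic level, a log2 difference of 1.31 (SE 0.14). Aldh1a2, which makes retinoic acid in limb-innervating motor neurons, averaged 601.7 ± 249 normalized counts at the brachial level and 5.43 ± 4.64 at the thoracic level (n = 3 each), 6.97 higher on the log2 scale (SE 0.78). Nos1, the nitric oxide synthase of preganglionic motor neurons, averaged 97.0 ± 13.6 at the brachial and 476.7 ± 78.5 at the thoracic level (n = 3 each), 4.88-fold higher in thoracic libraries. Kitl, which encodes Kit ligand, averaged 58.7 ± 13.2 and 660.6 ± 352 in the same order.

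All 10 Hox genes in the list passed the limma test. The 5 from paralog groups 1 to 8 were higher at the brachial level by 1.06 to 1.31 on the log2 scale, namely Hoxb8, Hoxa2, Hoxc4, Hoxc5 and Hoxc6. The 5 from paralog groups 9 to 13 were higher at the thoracic level, with Hoxc9 (log2 difference -1.07, SE 0.18) the smallest and Hoxa9 at -2.02 (SE 0.15). Hoxd9, Hoxa10 and Hoxc10 had few or no reads in brachial controls, with 13, 8 and 4 reads over the 3 libraries if 1 step is 1 read, so the size of their log2 differences of -5.34 (SE 1.15), -5.92 (SE 1.02) and -7.53 (SE 0.76) depends on the pseudocount. Hoxc5 and Hoxc10 share exon sequence in the reference annotation, and their counts are uncertain for that reason. Adjusted over the list alone, from the p-values of the authors' deposited table with unlisted members set to a p of 1, 5 of 32 names in the first Hox list and 5 of 20 in the second passed, and in each other fixed list every listed member passed in all 3 tables. The listed members were already selected by the authors on these p-values, so this repeats that selection and is no further test.

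**Figure D1:**
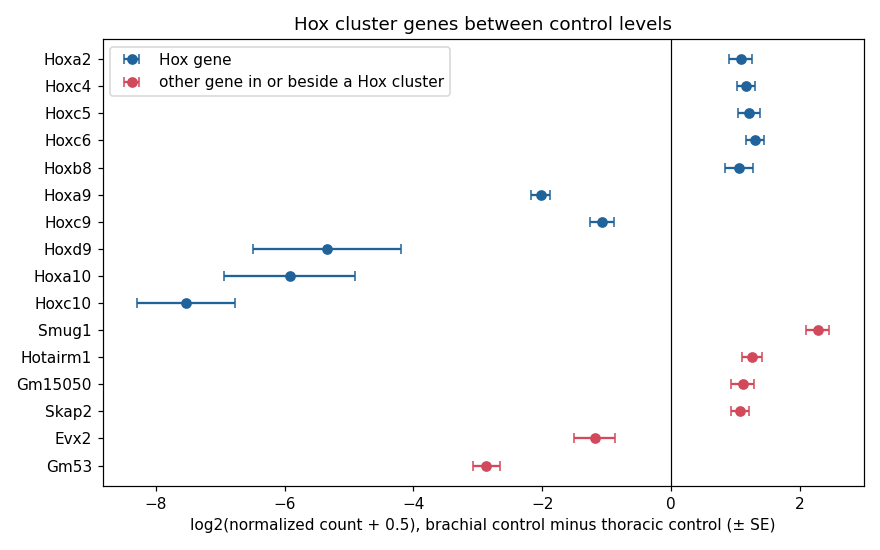
Log2 difference between brachial and thoracic control libraries (brachial minus thoracic, log2 of the normalized count + 0.5, points, with SE bars, 3 libraries per group) for the 10 listed Hox genes and 6 other listed genes within or next to a Hox cluster. Hoxa2 to Hoxb8 lie above 0 and Hoxa9 to Hoxc10 lie below 0.

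Of the lateral motor column and limb pool list, 5 of 22 genes were listed and all 5 passed. Aldh1a2, Runx1 and Etv4 were higher at the brachial level, Runx1 by 3.19 on the log2 scale (SE 0.78) and Etv4, an ETS factor of limb motor pools, by 2.94 (SE 0.54), while Npr3 (-1.58, SE 0.42) and Etv1 (-1.05, SE 0.21) were lower there. In thoracic controls, Aldh1a2, Runx1 and Etv4 rested on 20, 20 and 16 reads over 3 libraries if 1 step is 1 read. The hypaxial list gave Kitl and Etv1 and the preganglionic list gave Nos1, all higher in thoracic libraries. Thoracic control library C held more Kitl than A and B in the thoracic mutant table, 1228 normalized counts against 506.3 and 548.5. Among secreted signals, Igf1 (2.04, SE 0.25) and Inhba (2.16, SE 0.33) were higher at the brachial level and Fgf10 (-1.86, SE 0.33) was higher at the thoracic level. Other large differences were Dio3 (2.70), Tacr3 (2.77) and Smug1 (2.28), higher at the brachial level, and Mme (-2.94), Pkd2l1 (-2.53) and Crp (-2.14), higher at the thoracic level, and the channel-interacting gene Kcnip4 was also higher there (-1.27, SE 0.34). If 1 step is 1 read, Dio3 and Tacr3 rested on 12 reads each over the 3 thoracic control libraries. Pkd2l1 and Fgf10 rested on 22 and 25 reads over the 3 brachial control libraries. The sizes of these 4 differences are therefore less well known. Of the spinal interneuron list, 1 of 40 genes was listed, Evx2, at -1.18 (SE 0.32).

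Across the table, 63 of 64 listed genes passed limma at an adjusted p under 0.05, 23 higher at the brachial level and 40 higher at the thoracic level, and Necab1 (1.29) did not. It passed without brachial control C (1.79) or thoracic control A (1.61) and under some other settings. The libraries of the groups did not overlap for 63 genes. Chance gives 10% for genes that were not selected, but the listed genes were selected on these same libraries, so this count is no test. With each library centred on the median listed gene, 35 genes passed, 24 higher and 11 lower, and Hoxc9, Cyp26b1, Etv1, Kcnip4, Npr3, Crp, Fgf10 and Evx2 no longer did. This centring moved the median listed difference from -1.14 to -0.19, so negative differences move toward or past 0 by it alone. The adjusted p-values of the authors' deposited table imply at least 268 genes under 0.05, of which it lists the 64 beyond a fold limit of 1 on the log2 scale.

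In thoracic motor neurons, Pbx3 was lower in the mutant. Pbx3 read 3256, 3150 and 3714 normalized counts in control libraries A, B and C and 2350, 2448 and 1950 in the mutant libraries, a log2 difference of -0.59 (SE 0.16, limma adjusted p = 0.0107). The deleted part of the gene is not given in the sources used here, so this RNA level does not check the labels. Nos1 of the preganglionic list and Kitl of the hypaxial list fell: Nos1 averaged 549.1 ± 90.1 in controls and 135.2 ± 31.9 in mutants (SD, n = 3 each), 4.09-fold lower, and Kitl averaged 760.9 ± 405 and 103.9 ± 24.8. Each library holds RNA of many sorted cells, so less RNA per cell and fewer cells of a column cannot be told apart. Etv4, expressed in limb pools, rose from 5.18 ± 3.61 to 46.1 ± 13.7 (n = 3 each). Bmp4, a secreted signal, was at 1, 2 and 1 reads in the control libraries if 1 step is 1 read, and averaged 39.9 ± 14.7 normalized counts in mutants, so that its log2 difference of 4.45 (SE 0.30) depends on the pseudocount.

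**Figure D2:**
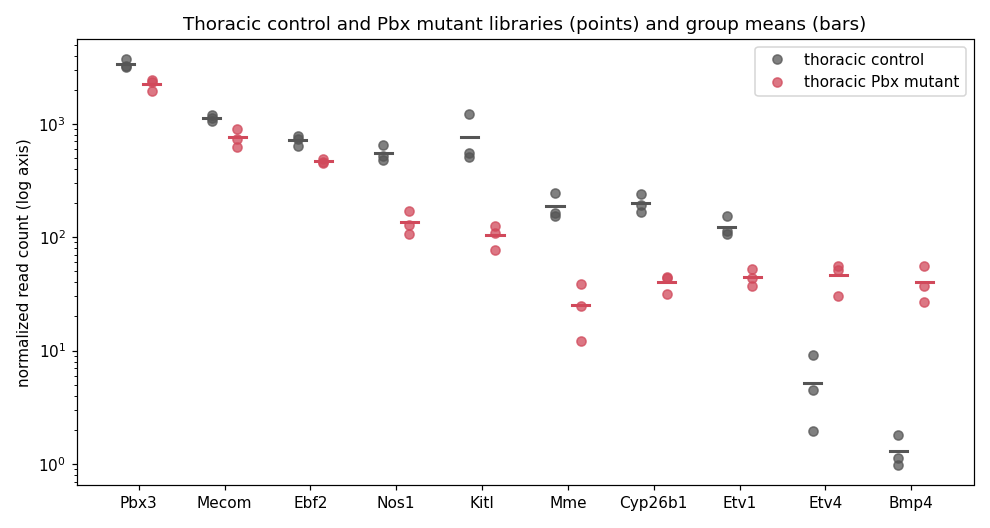
Normalized read counts (log axis) of 10 genes in thoracic control and thoracic Pbx mutant libraries, with 3 libraries per group as points and group means as bars. Etv4 and Bmp4 lie higher in mutants and the other 8 genes lie lower.

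Of the hypaxial motor column list, 3 of 6 genes were listed and all 3 fell, Kitl (log2 difference -2.77, SE 0.36), Etv1 (-1.47, SE 0.21) and the motor neuron factor Ebf2 (-0.62, SE 0.14). The 2 listed genes of the 10 preganglionic genes fell, Nos1 (-2.03, SE 0.21) and Zeb2 (-0.63, SE 0.17). Of the median motor column list, Ebf2 and Mecom (-0.58, SE 0.17) fell and Ebf1 (-0.29, SE 0.14) did not pass. The limb pool list gave 1 gene higher, Etv4, and 2 lower, Etv1 and Npr3 (-1.60, SE 0.31). All 5 listed channel and receptor genes were lower, among them Kcnip4 (-1.81, SE 0.23) and Cacna1e (-1.05, SE 0.22). The axon guidance genes Ntng1 (-0.67, SE 0.18) and Unc5c (-0.54, SE 0.14) were lower too. Of all 130 listed thoracic genes, 103 were lower, so falls within these lists follow the direction of most listed genes. Among adhesion genes, Cdh12 (0.77, SE 0.14) and Pcdh19 (0.43, SE 0.13) rose and Cntn2 (-0.42, SE 0.14) fell. Of the secreted signalling list, Bmp4 was higher and Cxcl12 (-2.32, SE 0.49), Bmp7 (-1.71, SE 0.33), Rxra (-0.77) and Tgfb2 (-0.58), among others, were lower. With each library centred on the median listed gene, the differences of Pbx3, Mecom, Ebf2, Zeb2, Unc5c, Tgfb2, Cacna2d1, Kcnb2, Nes and Cntn2 turned positive and did not pass, and Ebf1 turned positive and passed. Those of Cacna1e, Ntng1 and Rxra, among others, stayed negative and no longer passed. The median listed thoracic difference went from -0.67 to -0.03 under this centring, so small falls turn positive by it alone.

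Besides Kitl, Cxcl12 and Muc4, the largest falls were in Mme (-3.00, SE 0.41), Pkd2l1 (-2.60, SE 0.16), Creb5 (-2.47, SE 0.31), Crp (-2.41, SE 0.38) and Cyp26b1, a retinoic acid degrading enzyme (-2.30, SE 0.20). Muc4, with 4 reads over the 3 mutant libraries if 1 step is 1 read, was also lower. Besides Etv4 and Bmp4, Ppp1r1c (2.23, SE 0.39), Slc7a11 (1.97, SE 0.49), Ramp3 (1.77, SE 0.34), Spry4 (1.54, SE 0.22) and Cpne5 (1.41, SE 0.33) rose, and Stx11 rose from 4 reads over the control libraries. Of the mesenchyme and muscle list, 1 of 28 genes was listed, Postn, which averaged 35.4 ± 7.96 in controls and 7.91 ± 2.49 in mutants, and of the progenitor and glial list 1 of 26, Nes, which averaged 597.8 ± 99.5 and 428.3 ± 16.5 (SD, n = 3 each).

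In total, 123 of 130 listed thoracic genes passed limma at an adjusted p under 0.05, 25 higher and 98 lower in mutants, and the libraries of the groups did not overlap for 127. With the centring, 59 genes passed, 30 higher and 29 lower. Smug1, 0.47 higher (SE 0.19), lost its call without any one library other than thoracic control C, with differences between 0.32 and 0.56. Single left-out libraries also ended the calls of Cntn2 (mutant A, control A or control B; differences -0.37, -0.39 and -0.37), Nes (mutant A, mutant B or control B; -0.44, -0.48 and -0.34), Kcnb2 (mutant A or control B; -0.46 and -0.42), Mecom (mutant A; -0.46), Pcdh19 (mutant A; 0.41) and Chrm2 (mutant B; -0.67).

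In brachial motor neurons, the 4 listed genes of the 17 general motor neuron genes were lower in the mutant. Of all 62 listed brachial genes, 52 were lower, so this direction is not particular to motor neuron genes. Chat, the enzyme that makes acetylcholine, averaged 167.5 ± 34.6 normalized counts in controls and 58.2 ± 17.3 in mutants (SD, n = 3 each), 2.91-fold lower, and Slc5a7, the choline transporter, averaged 560.3 ± 113 and 372.0 ± 77.9, with libraries that overlap between the groups. Pbx3 read 2461, 2710 and 3121 in control libraries A, B and C and 1980, 1814 and 1506 in the mutant libraries, a log2 difference of -0.65 (SE 0.15, limma adjusted p = 0.00646). Cdkn1a, an inhibitor of the cell cycle, rose by 1.04 (SE 0.16).

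The log2 differences of these 4 genes were Chat (-1.54, SE 0.25), Ebf2 (-0.88, SE 0.12), Prph (-0.69, SE 0.19) and Slc5a7 (-0.59, SE 0.21). Of the median motor column list, Ebf2, Mecom (-0.82, SE 0.18) and Nr2f2 (-0.52, SE 0.19) fell. The 4 listed axon guidance genes were Sema5a (-0.45), Unc5c (-0.42), Slit2 (-0.40) and Plxna4 (-0.28), all lower. Among adhesion genes, Cntn2 (-0.68, SE 0.15) and Cdh6 (-0.52, SE 0.16) were lower and Cdh8 (0.40, SE 0.14) and Tenm3 (0.33, SE 0.13) were higher. Of the transcription factor families, 8 genes were listed, of which 7 fell, Nfia (-1.09, SE 0.14) the most. The preganglionic list gave Zeb2 (-0.41, SE 0.13). The largest falls were in Cyp26b1 (-2.78, SE 0.43), Creb5 (-2.39, SE 0.30), Arhgap36 (-2.10, SE 0.44), Hrk, which promotes cell death (-1.97, SE 0.21), H19 (-1.76, SE 0.13) and Chodl (-1.57, SE 0.21). Arhgap36 did not pass in the authors' own model (adjusted p = 0.0908), and its brachial control libraries ran from 158.0 to 552.8 normalized counts. Ak5 (1.17, SE 0.27), Cpne5 (1.15, SE 0.18), Lmo7 (1.03, SE 0.13), Igfbp2 (0.98, SE 0.16) and Dgkk (0.67, SE 0.16) rose.

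In total, 61 of 62 listed brachial genes passed limma at an adjusted p under 0.05, 10 higher and 51 lower, and the groups did not overlap for 60. Without brachial control B, 40 passed. With the centring, 23 passed, 11 higher and 12 lower, and the differences of Nr2f2, Sema5a, Slit2, Unc5c, Plxna4, Zeb2 and Cdh6 turned positive and did not pass, while Pbx3, Mecom, Prph, Slc5a7 and Cntn2, among others, stayed negative and no longer passed. Here too the centring moved the median listed difference, from -0.62 to -0.05, so small falls turn positive by it alone. Leaving out control B alone ended the calls of Cdh6 (-0.39), Nr2f2 (-0.47), Plxna4 (-0.26), Sema5a (-0.38), Slc5a7 (-0.47), Slit2 (-0.36), Tenm3 (0.36), Unc5c (-0.30) and Zeb2 (-0.32). Mutant B alone did so for Cdh6, Cdh8, Plxna4, Sema5a, Slc5a7, Slit2, Tenm3, Unc5c and Zeb2, control A for Sema5a and Tenm3, and control C, mutant A or mutant C for up to 7 of these genes, with Cdh8 between 0.28 and 0.42 and Plxna4 between -0.29 and -0.23 over the libraries that ended their calls.

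For the 30 genes of both mutant tables, the mutant effect did not pass a test of difference between the levels. These genes were selected by the authors at both levels, which favours similar effects and leaves out genes changed at 1 level only. All 30 had the same direction at both levels, with 26 lower and 4 higher in mutants. Limma called 27 of them in both tables, while Rapgef6, Arhgap5 and Fat1 did not pass at the thoracic level. At the thoracic and brachial level, the log2 differences were -2.47 (SE 0.31) and -2.39 (SE 0.30) for Creb5, -0.59 and -0.65 for Pbx3, -2.30 and -2.78 for Cyp26b1, and 1.41 and 1.15 for Cpne5. The limma interaction test called 0 of these 30 genes, and 0 had an unadjusted p under 0.05. The smallest unadjusted p was 0.0950, for H19, with an adjusted p of 0.858. The 95% interval of the difference reached 0.57 to either side on the log2 scale for the median gene and 1.41 for the widest, so smaller differences are not excluded. Genes listed at 1 level only, such as Nos1, Kitl, Etv4 and Chat, could not be tested, since their values at the other level were not analysed here.

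**Figure D3:**
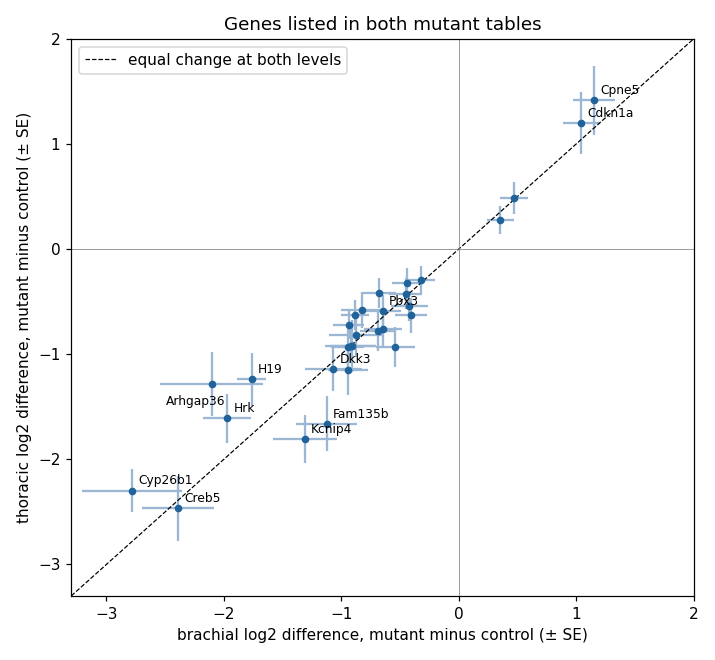
Log2 difference between mutant and control (log2 of the normalized count + 0.5, points, with SE bars) at the brachial level (horizontal) and thoracic level (vertical) for the 30 genes listed in both mutant tables. The dashed line marks equal change, and all 30 genes share their direction.

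Of the 64 genes listed between control levels, 21 were also listed in the thoracic mutant table. All 21 had the direction that brings thoracic mutants toward brachial controls. Unchanged genes past both thresholds share their direction in 100% of cases in the simulation below. This agreement alone therefore does not separate an effect of the mutation from the shared controls. Etv4 and Smug1 were higher in brachial controls and in thoracic mutants, and 19 genes were lower in both, among them Kitl, Mme, Nos1, Pkd2l1, Crp, Cyp26b1 and Kcnip4. None of the 10 listed Hox genes was among them. The 64 genes lie beyond a fold limit of 1 on the log2 scale, out of at least 268 under 0.05. The mutant lists hold smaller changes, down to 0.27 (thoracic) and 0.20 (brachial) in the authors' absolute log2 fold change. The overlap counts therefore compare lists made at unlike limits. Both comparisons used the thoracic control libraries: unchanged genes simulated against shared controls gave 0.26 genes past both thresholds, and independent lists would share 0.05 genes in the higher and 0.30 in the lower direction. The 3 control libraries could not be split with 2 in each part, and part of the excess may come from the shared controls. Control levels and brachial mutants shared 2 genes, Cyp26b1 and Kcnip4, both lower, where shared controls gave 0.29 genes in the simulation, with the same direction in 0% of those past both thresholds.

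**Figure D4:**
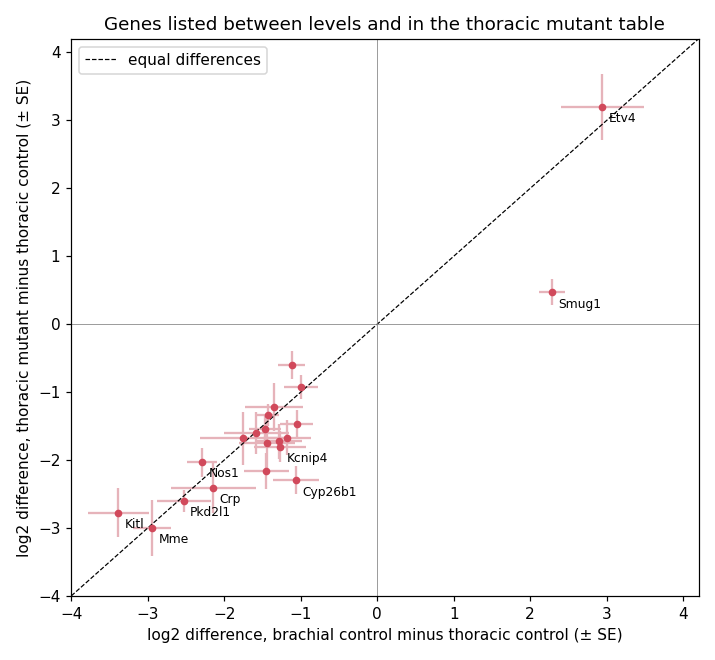
Log2 difference between brachial and thoracic controls (horizontal) and between thoracic mutants and thoracic controls (vertical), with SE bars, for the 21 genes listed in both tables. The dashed line marks equal differences, and Smug1 lies far below it at 2.28 and 0.47.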

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

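The limits on the log2 difference used in every table, and the authors' adjusted p under 0.05 alone, were chosen after seeing the data. Pseudocounts, the block, the intensity trend and the authors' adjusted p under 0.01 kept the total passing in each table within 1.5 times. Under the last, thoracic genes higher in mutants went from 25 to 16 and some list counts moved further, such as brachial axon guidance and adhesion genes, each from 4 to 2, and thoracic channel and receptor genes, from 5 to 3. The minimum mean of 1 removed no gene. The planned count-model tests were not run, since the unit used here is a normalized signal. Centring on the median listed gene left 35, 59 and 23 genes between control levels, in thoracic and in brachial mutants, and moved the median log2 difference from -1.14 to -0.19, -0.67 to -0.03 and -0.62 to -0.05. Because the genes were selected and mostly lower, this follows from the centring itself. It reversed 22 differences of named genes: in thoracic mutants Cacna2d1 (0.11), Cntn2 (0.22), Ebf1 (0.36), Ebf2 (0.019), Egr1 (0.042), Jun (0.19), Kcnb2 (0.17), Klf6 (0.25), Mecom (0.061), Nes (0.17), Pbx3 (0.055), Spry2 (0.057), Tgfb2 (0.063), Unc5c (0.10) and Zeb2 (0.015), and in brachial mutants Cdh6 (0.039), Nr2f2 (0.040), Plxna4 (0.29), Sema5a (0.11), Slit2 (0.17), Unc5c (0.14) and Zeb2 (0.16). An authors' absolute log2 fold change of at least 2 left 18 genes between control levels, 16 in thoracic mutants and no gene of the brachial table. It also left 5 of the 21 genes shared between levels and thoracic mutants. This limit is not alike across comparisons, since the authors' brachial log2 fold changes reached 1.06 at most in absolute value. Recomputed from normalized counts, the brachial differences of Cyp26b1 (-2.78), Creb5 (-2.39) and Arhgap36 (-2.10) lay beyond 2. An own difference of at least 1 left 54 thoracic and 17 brachial genes. Leaving out 1 library gave 61 to 64 genes between control levels, 100 to 114 in thoracic mutants, 40 (without brachial control B) to 58 in brachial mutants and 0 to 0 for the interaction. The alternatives other than limits on the authors' values or on the log2 difference were also applied to the 119 differences of named genes. They gave 1310 values with the same side and call, 89 that lost the call, 7 that gained it and 22 that changed side. No label says that the letters A to C pair the libraries. Same-letter correlations of the deviations from the group mean ran from -0.49 to 0.31, and between control levels they were 0.29, -0.03 and 0.16. With 3 libraries per group these values cannot show whether the libraries are paired, so this stays open. With the letter as a block, 64, 118 and 60 genes passed, and 0 for the interaction, and not every library correlated best with its own letter. The few reads of Hoxc10, Bmp4, Stx11 and Muc4 in 1 group limit how well their folds are known.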

Other observations

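The genes of this paragraph, other than Olig3 and Spry4, were picked after their values were seen, from a list in which most genes were lower. Of immediate-early genes, Egr1 averaged 1193 ± 217 normalized counts in thoracic controls and 779 ± 38.7 in mutants (SD, n = 3 each), and Jun (-0.45, SE 0.17), Nr4a3 (-0.81, SE 0.21) and Klf6 (-0.39, SE 0.15) were lower too. Control library C had the highest values of Egr1 and Jun, 1438 and 2159. Olig3, a gene of dorsal progenitors, was at 55.5 ± 9.54 in controls and 17.1 ± 1.54 in mutants, and Col2a1, a gene of cartilage, at 77.4 ± 27.6 and 34.7 ± 3.37. Of feedback genes of receptor signalling, Spry4 was higher by 1.54 (SE 0.22) and Spry2 lower (-0.59, SE 0.13). With each library centred on the median listed gene, the differences of Egr1, Jun, Klf6 and Spry2 turned positive and did not pass, and those of Nr4a3 and Col2a1 stayed negative and no longer passed. Small falls turn positive by the centring alone. Jun lost its call without any one library other than control B (differences between -0.49 and -0.31), and Klf6 without any one other than mutant A (between -0.43 and -0.33). Gm13404, with no protein-coding gene between it and Pbx3 and no exon shared with it, fell by 1.40 (SE 0.27) in thoracic mutants.

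All tests in this part were chosen after the results were seen. For the counts of genes passing limma, the 10 splits of 6 libraries into groups of 3 are too few for a share under 0.05. The real split gave 63, 123 and 61 genes between control levels, in thoracic and in brachial mutants, only 1 of the 10 splits, the real one, gave as many in each, and the highest of the other splits was 0. The listed genes were selected by the authors on the real split of these libraries, so this gap was built in and is no test. For the interaction, the real count of 0 is reached by any exchange of the level labels, here 100 of 100, the highest of the others being 5, so the exchanges say nothing there.

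The 21 genes shared between control levels and thoracic mutants had the direction of brachial values, as unchanged genes past both thresholds do in 100% of cases with shared controls. The simulation gave 0.26 such genes, but it left out genes changed in 1 comparison only. The direction alone therefore does not separate an effect of the mutation from the shared controls. Brachial control cells in the thoracic mutant samples are argued against as the whole cause. They would need 1 share for all genes, yet 7 of the 21 genes excluded the share of 0.961 that the most genes allowed: Smug1 needed 0.10 and Cyp26b1 1.56, above a whole sample. Brachial mutant cells in these samples are argued against as the whole cause as well, if unlisted genes keep brachial control levels in such cells. The 2 genes with a level in brachial mutants, Kcnip4 and Cyp26b1, needed shares of 0.87 and 0.86, at the lowest 0.77. Of the genes listed between levels, 43 are not listed in thoracic mutants. At 0.77, with brachial control levels, 10 of these 43 would lie more than 2 SE past the authors' thoracic mutant threshold. Among them were Hoxc6, Hoxa9 and Igf1. The ranks of the authors' p-values leave 2 unlisted genes under 0.05 in thoracic mutants and 1 in brachial mutants up to the last such listed rank. In brachial mutants that rank is 62 and the highest listed one is 81, so unlisted genes between them are not bounded. A smaller share of such cells stays open. Levels were set across tables through the shared controls. Thoracic control C alone is argued against, since 20 of the 21 genes passed in the thoracic mutant comparison without it. Of all 130 listed thoracic genes, 108 passed without that library, and all were selected with it included. Noise of the shared controls in unchanged genes is argued against as the whole cause. The simulation gave 0.26 such genes with a 95th percentile of 1, against 21 shared genes. For part of the overlap, noise of the shared controls stays open. The simulation leaves out genes changed in 1 comparison only, and the controls could not be split. An effect of the mutation on part of the genes that differ between levels stays open and was not tested apart from this noise. The other 43 genes listed between levels, with all 10 Hox genes, Aldh1a2 and Runx1 among them, were not listed in thoracic mutants.

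The authors' deposited table gave smaller brachial than thoracic log2 fold changes for 24 of the 30 shared genes, with a median ratio of 0.57. Computed alike from the normalized counts, the median ratio was 1.01 and 14 of the 30 were larger at the thoracic level. This is consistent with shrinkage in the authors' brachial model as the source of the gap, for genes selected at both levels. No biological explanation was tested.

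Genes other than Hox genes within or next to Hox clusters differed between control levels. Smug1, next to Hoxc4, Skap2, next to the HoxA cluster, Hotairm1 and Gm15050 were higher at the brachial level, and Evx2, next to Hoxd13, and Gm53, near Hoxb9, were higher at the thoracic level. In the reference annotation, 5 of these 6 genes share no exon with a Hox gene, which argues against shared exons for these 5 in that annotation only. The counts were made on another build, whose annotation was not checked. For the other 1, Hotairm1, shared exons stay open. All 6 had the direction of the nearest end of the cluster, but they were seen first, and 3 of them lie at 1 cluster. Counted per cluster, 4 of 4 matched (exact binomial test, two-sided p = 0.125, the smallest that 4 clusters can give), so a link to the side of the cluster is not shown and stays open. Transcription running on from Hox genes was not tested.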
